A study of Mus musculus with 30 samples.

How the data were processed

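Poly(A)-selected, stranded RNA-seq libraries of mouse iPSCs and retinal organoids were studied at 10 days, with 3 libraries per day. Per the labels' protocols, the material was iPSCs with feeders at D0, whole aggregates at D4 and dissected neural retina from D7. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36 and quantified with kallisto 0.42.4, a pseudoaligner that shares ambiguous reads between transcripts, on GRCm38.p4, and normalised with edgeR, version not given. Of 3 deposited tables, the first gives an estimated count per gene and the third an estimated count per transcript, as deposited by the authors. The step from transcripts to genes is not stated in the sources used here: library totals of the tables were equal, and of 19182 genes with a single transcript 51 had a gene value equal to the transcript value within 0.1% in every library. The second table holds a normalised signal per gene (CPM), deposited after TMM scaling by the authors per the submitters' processing notes. Within a library it was the gene table times 1 factor, its library totals lay between 843899 and 1918405 (median 963095.5), and its r with own TMM CPM was at least 0.99999. Each table also had 3 columns that match no listed sample (9 in all), which were not used.

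How the counting used strand is not stated, so a read from a gene and from its antisense or overlapping partner may not be told apart. Sharing of reads between near-identical copies by kallisto bears on genes with pseudogenes. The gene table held 45594 genes, of which 10845 had no count in any library, and 113468 transcripts stood in the other table of counts. Symbols were those of the deposited table, and 44828 identifiers had a name in GENCODE M21. Since 273 symbols belonged to more than 1 identifier, all tests used identifiers, and Cabp4 and Rp1 each entered their list with 2 identifiers.

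Gene estimates were rounded and tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the days as groups (minimum count 10, minimum total 15), which left 19897 genes and at least 99.73% of the counts of every library. Libraries were scaled by TMM over the kept genes (factors 0.524 to 1.162), and 1 model with a mean per day was fitted to all 30 libraries. The quasi-likelihood F test was used for each contrast, with Benjamini-Hochberg adjustment over the tested genes, and a gene was called changed at an adjusted p below 0.05. A test over all 10 days came first, then 3 spans (D7 vs D0, D18 vs D7 and D32 vs D18) and 9 steps between consecutive days. Depth lay between 16.77 and 24.53 M counts, so that 1 CPM stands for about 16.77 to 24.53 counts in a library. Counting error was thus small against the spread of replicates except for genes near 0. A gene with 0 counts on a day is given only as a bound, taken from 3 counts over the 3 libraries of that day.

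Before the data were examined, 30 gene lists with 375 genes were fixed from textbook knowledge. They cover pluripotency, mesendoderm, eye field and optic vesicle, retinal progenitors, neurogenic precursors, ganglion, amacrine, horizontal and bipolar cells, Müller glia, photoreceptor transcription factors, rods, cones, outer segment and cilium, ribbon synapse, pigment epithelium, proliferation, fibroblasts and feeders, telencephalon and hypothalamus, hindbrain and spinal cord, lens, microglia and blood, endothelium, neural crest and other glia, hypoxia, retinoid response, cholesterol synthesis, amino acid and ER stress, immediate early genes and mitochondrially encoded genes. Lists with at least 3 tested members were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation. Adjustment was over the 30 lists of a comparison. Beside some member counts the text gives those "alone", meaning adjusted over the members of that list instead of all tested genes.

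Genes named in the text follow a rule fixed in advance: in each span the 10 largest rises and falls, and in each step the 3 largest, among changed genes whose 3 libraries of the one day did not overlap those of the other and whose mean was at least 10 CPM on the higher day. Predicted genes and pseudogenes of histone, ribosomal and mitochondrial genes were passed over. Added to these were, for each list described, up to 4 changed members with the largest fold, the members that moved against the list and the highest member that did not pass, as well as 31 markers over the 10 days. Rpl3 and the genes named with the library sets in the closing section were chosen after their values were seen.

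Alternatives fixed before the data were examined were RLE factors, library size without factors, DESeq2 1.42.0, 2 other expression filters (no filter beyond 1 count, and a CPM of at least 1 in at least 3 libraries), limma on the deposited CPM with 1 or 0.1 added before the log, the replicate number as a block, only the 6 libraries of a pair of days, and leaving out each library. Those chosen after seeing the data were the removal of ribosomal RNA-like genes, of D4 or of D4 replicate 2, a fit to D10 to D25 with and without the block, the library set as a term, and each set alone. The replicate number was checked as a pairing by correlating residuals of libraries with the same number. Every such correlation passed 0.1 in the 5 steps from D10 to D25 and in none of the other comparisons, with a median of 0.208 (from −0.003 to 0.342) over 45 pairs on those days, against −0.124 over 90 pairs of different number. Residuals sum to about 0 over the libraries of a day, which by itself pushes pairs of different number below 0. From D10 to D25 the number also overlaps with the library sets defined below, with replicate 2 in set 1 and replicates 1 and 3 in set 2. A set difference can thus give part of these correlations. The labels do not say what the number means, so the unblocked model was kept and blocked values stand beside those steps.

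Library sets were defined by whether the pseudogenes of Rpl3 held under or over 50% of the counts of Rpl3 and its pseudogenes. That definition was chosen after other measures had not parted the libraries. Of 68 genes with a tested named pseudogene only Tma7, Rpl34 and Rpl3 parted the sets without overlap. The steps for genes, lists and transcript shares were tested on simulated data with known changes before use. The fits with library set as a term and with set 2 alone were run on simulated data only after their first use on the series. For simulated counts like those of D12 vs D10, log2 changes of 1 and 2 were recovered for 36% and 86% of the genes, those of −1 and −2 for 31.2% and 72%, with 8 false calls among 19603 genes and 0 of 50 random lists called by camera. Simulated genes varied independently of each other, so the 0 of 50 gives no error rate for lists of genes that move together.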

Results

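Transcriptome change during the formation of retinal organoids was followed in RNA-seq libraries from 10 collection days. The organoids were grown from 1 line of mouse induced pluripotent stem cells (iPSCs), reprogrammed from embryonic fibroblasts of Nrl-GFP mice. In these mice the promoter of Nrl, the transcription factor that sets rod identity, drives green fluorescent protein. Undifferentiated iPSCs on feeder cells were collected at day 0 (D0) and whole aggregates at D4. From D7 on only dissected neural retina was used, at D7, D10, D12, D15, D18, D22, D25 and D32. Each day had 3 libraries labelled as biological replicates, made from 36 organoids at D4, 30 at D7, 20 at D10 and 12 from D12 on. By the labels, the medium changed at D7, medium and oxygen (from 5% to 20%) changed together at D10, and the medium changed again at D26. The 30 libraries held 16.77 to 24.53 M estimated counts (median 19.23 M), and 19897 genes were tested. Levels below are mean CPM (counts scaled to a common library size) ± SD with n = 3 libraries a day, and log2 changes carry their standard error (SE).

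The libraries separated mainly by day. Day by day, the correlation of replicate libraries lay between 0.9485 and 0.9883, with the lowest value at D4. The biological coefficient of variation was 0.42 at D4, 0.257 at D12 and between 0.153 and 0.221 on the other days. D4 replicate 2 held 29.756% counts from ribosomal RNA-like genes, against at most 0.352% elsewhere, and had a scaling factor of 0.524. D4 replicate 3 lay closer to the mean of D7 (r = 0.9611) than to the mean of the other D4 libraries (r = 0.9597). On D15 and D22 replicate 2 was nearest to the following day (0.9827 against 0.9823 and 0.9859 against 0.9825).

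**Figure D1:**
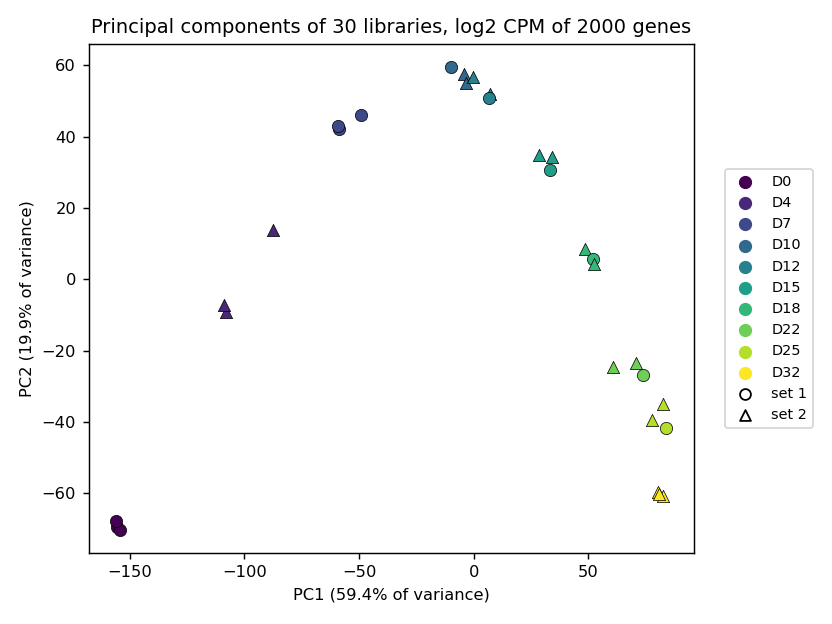
Principal components of the 30 libraries from log2 CPM of 2000 genes, coloured by day and shaped by library set. The first component held 59.4% and the second 19.9% of the variance.

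After the data were examined, the libraries were also found to fall into 2 sets by how counts were shared between genes and their processed copies. Pseudogenes of Rpl3, a ribosomal protein gene, took 12 to 31.8% of the counts of Rpl3 and its copies in 12 libraries (set 1) and 70.9 to 86.5% in the other 18 (set 2). Set 1 held all libraries of D0 and D7 and replicate 2 of each day from D10 to D25. Set 2 held all libraries of D4 and D32 and replicates 1 and 3 of D10 to D25. With day in the model, 861 of 18291 genes differed between the sets over D10 to D25 (417 higher and 444 lower in set 1, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Among the 326 tested list genes 25 differed, and the size is given below where such a gene is named. Counts with the set as a term in the model stand beside each comparison.

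**Figure D2:**
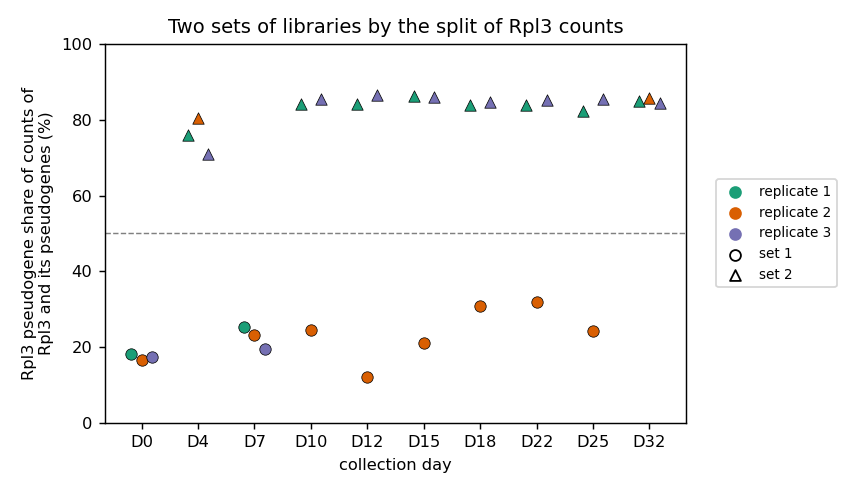
Share of Rpl3 pseudogenes in the counts of Rpl3 and its pseudogenes, per library and day. Set 1 lay between 12 and 31.8% and set 2 between 70.9 and 86.5%.

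Which genes changed over the 10 days, and in what order did known markers peak? Pluripotency genes were highest at the start. Pou5f1, a core pluripotency factor (ENSMUSG00000024406, chromosome 17, 35506018 to 35510772, GRCm38.p4), stood at 957 ± 188 CPM at D0, 294 ± 270 at D4 and 15.6 ± 1.82 at D7. Six3, an eye field transcription factor, reached 69.3 ± 26 CPM at D4, and Pax6, the master regulator of eye development, 406 ± 42.4 at D7 and 730 ± 102 at D15. Rax, a factor of retinal progenitors, peaked at D15 with 193 ± 46.8 CPM. Mki67, made in dividing cells, was at 747 ± 159 CPM at D12 and 20.4 ± 2.82 at D32.

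Markers of the early-born neurons were highest at D10 to D25. Atoh7, required for ganglion cell competence, reached 84.3 ± 24.9 CPM at D15, as did Pou4f2, a ganglion cell factor, with 52.4 ± 26.1, and Onecut1 of horizontal cells with 59.8 ± 4.48. Ptf1a, which directs amacrine and horizontal fate, was highest at D18 (9.61 ± 1.23 CPM), and Tfap2b of amacrine cells at D25 (350 ± 94.9). Crx, the photoreceptor homeobox factor, passed from 39.3 ± 11.9 CPM at D12 to 1210 ± 132 at D32. Nrl (chromosome 14, 55518978 to 55524981) went from 5.37 ± 2.78 CPM at D15 to 344 ± 120 at D22 and 881 ± 252 at D25. Opn1sw, the short-wave cone pigment, was highest at D25 (77.7 ± 39.9 CPM), while the medium-wave cone pigment Opn1mw was at 0 on every day but D7 (0.012 ± 0.0207 CPM). Rlbp1 of Müller glia (164 ± 37.1 CPM) and Grm6, the glutamate receptor of ON bipolar cells (79.6 ± 8.35), were highest at D32. Glul, the other Müller glia gene among the markers, was highest at D10. Rpe65, an enzyme of mature pigment epithelium, stayed at or below 0.0623 CPM.

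**Figure D3:**
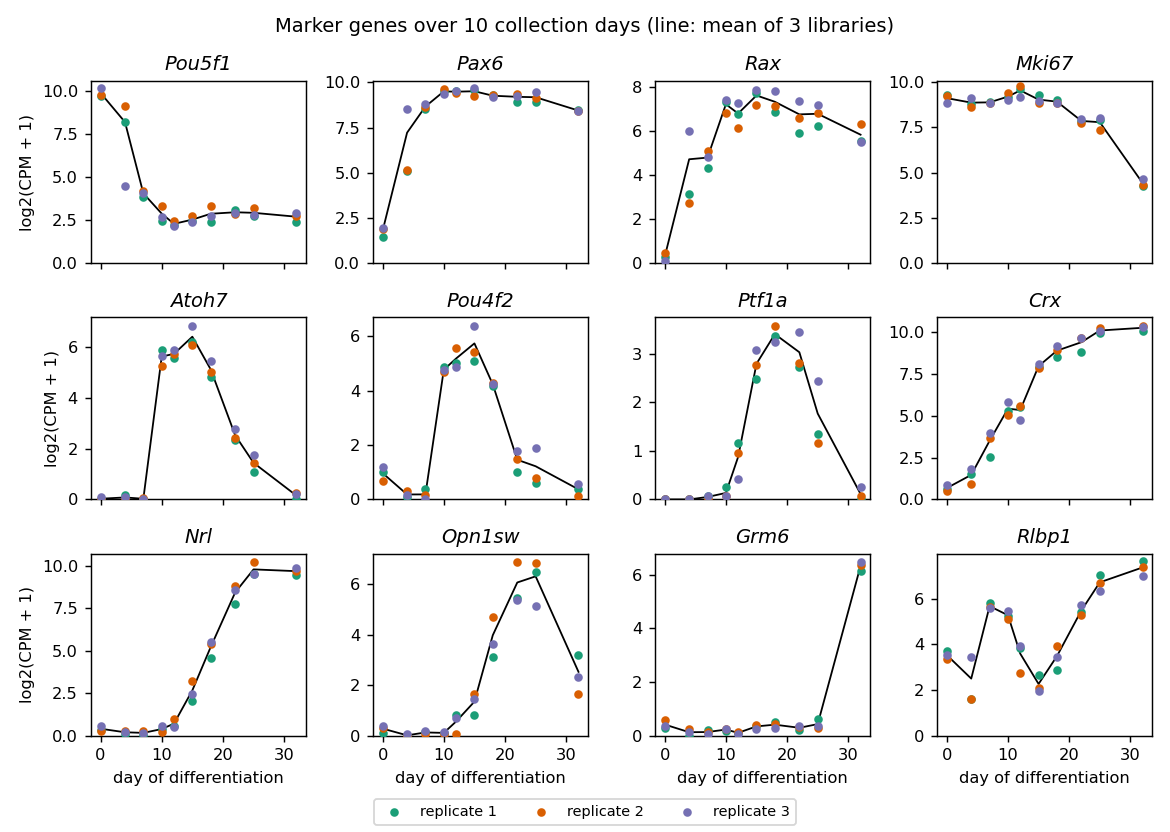
Marker genes over the 10 days as log2(CPM + 1), 1 point per library and a line through the means of 3 libraries. Nrl went from 5.37 ± 2.78 CPM at D15 to 344 ± 120 at D22.

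In the quasi-likelihood F test over all days 18178 genes changed (91.4% of those tested), and 18128 with the set as a term. The largest groups peaked at D0 (4327 genes), D32 (3894) and D4 (2890), and the smallest at D18 (402). Since most genes changed, the sections below take the days pairwise, first over 3 long spans and then step by step.

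**Figure D4:**
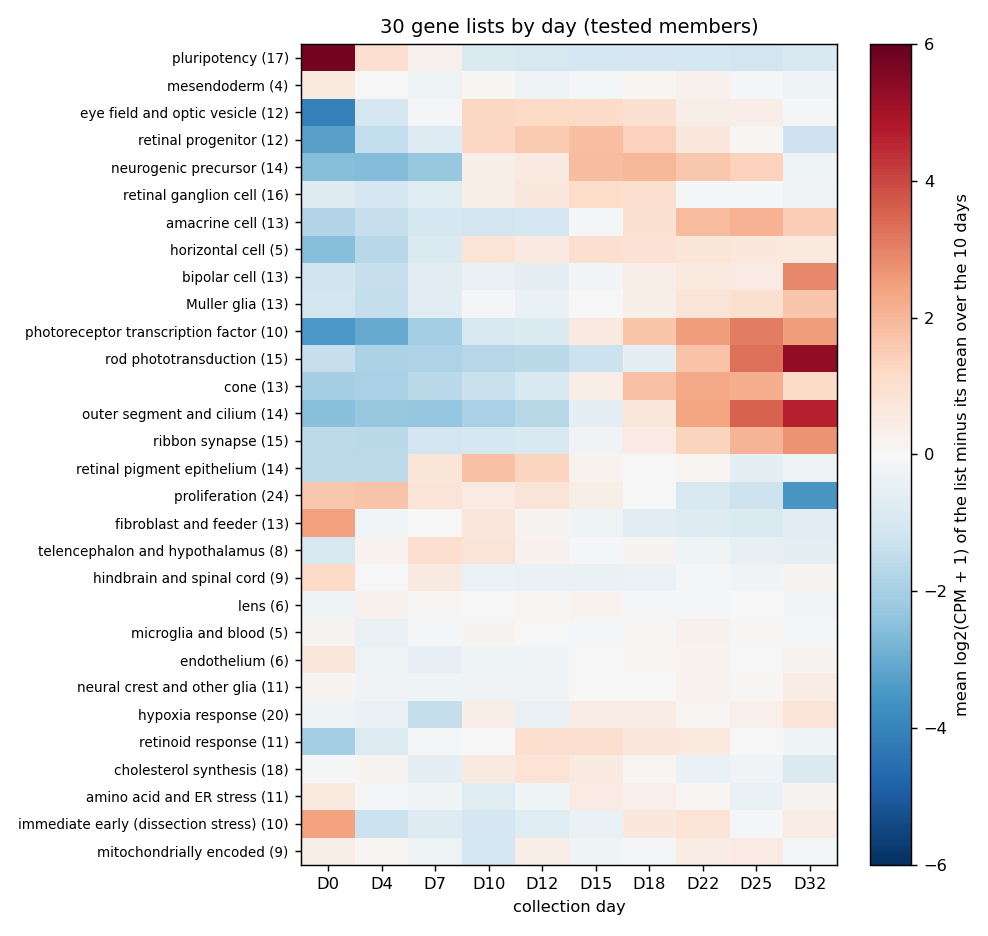
Mean log2(CPM + 1) of the tested members of 30 gene lists by day, relative to each list's mean over the 10 days. The lists were fixed before the data were examined.

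What separated neural retina at D7 from iPSCs at D0? The pluripotency programme was lost. All 17 pluripotency genes fell (median log2 −5.98, camera adjusted p = 8.7e-29, and 3.1e-07 with an estimated correlation). Tdgf1, a NODAL co-receptor (ENSMUSG00000032494, chromosome 9, 110939603 to 110946158), went from 659 ± 151 to 1.85 ± 0.622 CPM (log2 −8.48, SE 0.39, adjusted p = 4.6e-15). Esrrb, a nuclear receptor of the naive state, fell from 616 ± 45.5 to 4.78 ± 0.536 CPM (−7.01, SE 0.27) and Fgf4, the growth factor of early embryo cells, from 211 ± 34.6 to 1.37 ± 0.514 (−7.27, SE 0.42). The pigment gene Dct (ENSMUSG00000022129, chromosome 14, 118012792 to 118052246) had no counts at D0 and stood at 164 ± 7.94 CPM at D7, at least 3000-fold higher. Such floors rest on 3 counts over a day's 3 libraries and cover counting error only.

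Eye field genes rose beside it: 9 of 12 were higher and 2 lower (median log2 7.13, adjusted p = 2.9e-06, and 0.16 with an estimated correlation). Lhx2, needed to form the optic vesicle, rose to 188 ± 24.3 CPM (8.35, SE 0.74) and Mab21l1 to 53 ± 7.43 (8.44, SE 0.83), while Fzd5, a WNT receptor, fell from 116 ± 3.3 to 57.1 ± 9.4 (−1.03, SE 0.21). Six3 was at 0.0552 ± 0.0957 and 60.5 ± 13.9 CPM. Among progenitor genes 9 of 12 rose and 2 fell, Sox2 and the cyclin Ccnd1 (−1.79, SE 0.24 and −1.27, SE 0.3), with adjusted p = 0.0012, and 0.2 with an estimated correlation. In the pigment epithelium list 9 of 14 rose and Mlana fell (median log2 4.09, or 3.63 with floors, adjusted p = 0.0012, and 0.37 with an estimated correlation). Slc45a2, a melanosome transporter, was at least 270-fold higher (15 ± 2.6 CPM). Photoreceptor factors (5 of 10 higher, 2 lower, median 1.75, adjusted p = 0.0012, and 0.28 with an estimated correlation) included Otx2 (411 ± 48.4 CPM, 4.88, SE 0.19), while the repressor Prdm1 fell (−4.78, SE 0.37). Horizontal cell genes (4 of 5 higher, median 2.94, adjusted p = 0.012, and 0.2 with an estimated correlation) were led by Onecut2 (3.99, SE 0.3) and Prox1 (3.48, SE 0.38).

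The retinoid list held 7 higher and 1 lower of 11 (median log2 2.18, adjusted p = 0.0024, and 0.2 with an estimated correlation). Crabp2, which carries retinoic acid, rose from 11.7 ± 0.372 to 551 ± 38.2 CPM and Stra6, a retinol transporter, to 88.7 ± 8.54. Falling lists included proliferation, 20 of 24 lower (median −0.84, adjusted p = 0.0012, and 0.58 with an estimated correlation), with Ccnb1, the mitotic cyclin, going from 614 ± 21.2 to 205 ± 9.79 CPM. Mki67 (555 ± 90.6 and 472 ± 9.01) did not pass (adjusted p = 0.26). Fibroblast and feeder genes had 10 of 13 lower (median −2.92, adjusted p = 0.037, and 0.61 with an estimated correlation), such as the collagen Col1a1 (237 ± 142 to 5.23 ± 0.139 CPM). The labels name feeders at D0, and that list moved with the pluripotency list. Hypoxia genes were lower for 12 of 20 (median −0.84, adjusted p = 0.024, and 0.61 with an estimated correlation), among them Hk2, a glycolytic enzyme (−2.83, SE 0.35). All 10 immediate early genes fell (median −3.66, adjusted p = 0.0012, and 0.5 with an estimated correlation), with Egr1 going from 424 ± 19.9 to 14.5 ± 6.52 CPM.

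Beyond the lists, the largest rises were in Inmt, Tspan10, Lmo3, Wnt1 and Tmem200c, with no counts at D0 and at least 1300, 510, 320, 310 and 180-fold higher levels at D7. Wnt8b, a WNT ligand of the forebrain margin, reached 139 ± 33.5 CPM (10.77, SE 1.54), and Fezf2, a forebrain factor, 37.5 ± 3.04 from 0.0377 ± 0.0327. Rbpsuh-rs3 and Xlr5b had no counts at D7 and were at least 310-fold and 210-fold lower. Usp26 (109 ± 11.3 to 0.111 ± 0.0961 CPM), Vwa3b and Krt42 fell (log2 −9.89, −8.57 and −8.53), and Xlr5a and S100a4 went from 18 ± 2.28 and 31.3 ± 11.8 CPM to below 0.1, and Krt17 was at 0.018 ± 0.0311 CPM at D7. Fthl17c was at 10.9 ± 0.851 CPM at D0 and 0 at D7.

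The other lists did not pass camera at this span (adjusted p from 0.063 to 0.83): mesendoderm 3 of 4 lower (0.41), neurogenic 8 higher and 3 lower of 14 (0.55), ganglion cell 8 and 6 of 16 (0.83), bipolar 4 and 3 of 13 (0.67), Müller glia 7 and 3 of 13 (0.41), rod 5 of 15 lower (0.41), cone 5 and 3 of 13 (0.21), outer segment 4 and 3 of 14 (0.67), ribbon synapse 4 and 6 of 15 (0.67), telencephalon 5 and 1 of 8 (0.063), lens 2 higher of 6, 1 when adjusted over the list alone (0.62), microglia 1 of 5 lower (0.67), endothelium 1 and 3 of 6 (0.21), neural crest 2 and 4 of 11 (0.43), cholesterol 8 of 18 lower (0.28), amino acid and ER stress 1 and 7 of 11, 2 and 7 alone (0.063), and mitochondrially encoded 3 of 9 lower, 2 alone (0.32). The amacrine list (5 and 4 of 13, 0.44) had a median of −0.02, a mean of 0.48 and an upward test, the bipolar list a median of −0.15, a mean of 1.22 and an upward test, and the hindbrain list (1 and 4 of 9, 0.41) a median of 0.14, a mean of −0.91 and a downward test. Trpm1, an ion channel of bipolar and pigment cells, stood out within its list with 870 ± 79.8 CPM at D7 (8, SE 0.76). In all, 11622 genes changed, 5725 higher and 5897 lower at D7 (6494 and 4712 with library size only). Both days lie in set 1, and the 12 set 1 libraries alone gave 12163 changed genes and a model with the set 11784. D0 cells were not dissected, so day and dissection changed together.

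What changed between D7 and D18, when the neural retina grows and makes its first neurons? Neurogenic genes rose together: all 14 tested were higher (median log2 5.04, adjusted p = 1.5e-24, and 0.00035 with an estimated correlation). Foxn4, a progenitor factor for amacrine and horizontal fates, rose by 7.76 on the log2 scale (SE 0.39) from 0.583 ± 0.38 CPM, Neurod4 to 235 ± 30.2 (6.91, SE 0.44) and Neurog2 to 124 ± 46 (6.97, SE 0.61), while Atoh7 (ENSMUSG00000036816, chromosome 10, 63100156 to 63100605) went from 0.018 ± 0.0311 to 33.9 ± 7.95. Photoreceptor factors rose for 8 of 10 (median 5.17, adjusted p = 9e-15, and 0.004 with an estimated correlation). Nr2e3, which represses cone genes in rods (ENSMUSG00000032292, chromosome 9, 59942771 to 59960659), had no counts at D7 and was at least 430-fold higher at D18 (24.1 ± 14 CPM). Over D10 to D25 its log2 level was 0.99 higher in set 1 than in set 2.

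Cone genes rose for 12 of 13 (median log2 4.68, adjusted p = 2.7e-10, and 0.006 with an estimated correlation). The transducin subunits Gngt2 and Gnb3 reached 182 ± 41.9 and 215 ± 56.1 CPM (10.63, SE 0.64 and 6.76, SE 0.37), and Opn1sw 14.6 ± 9.02 (7.24, SE 0.85, with a set 1 excess of 1.01). The outer segment and cilium list had 10 of 14 higher (median 5.14, or 4.36 with floors, adjusted p = 2.2e-13, and 0.0052 with an estimated correlation), among them Cdhr1 (353 ± 29.4 CPM, 8.27, SE 0.33), Prph2 (29.8 ± 8.96, 6.95, SE 0.54) and the microtubule protein gene Rp1l1 (45.2 ± 5.2 CPM). Ribbon synapse genes rose for 12 of 15 (median 1.99, adjusted p = 2.9e-07, and 0.024 with an estimated correlation), such as the glutamate transporter Slc17a7 (46.3 ± 5.27 CPM, 7.05, SE 0.32). Of 15 rod genes 7 rose (median 1.6, adjusted p = 0.0077, and 0.34 with an estimated correlation), with Pdc, which binds transducin, at 93.5 ± 30.3 CPM (9.28, SE 0.6, adjusted p = 4.4e-12). Gnb1 (522 ± 13.6 and 465 ± 18.8) did not pass.

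Genes of the inner retina moved up as well. Ganglion cell genes were higher for 13 of 16 and lower for Rbpms (median log2 1.87, adjusted p = 0.00095, and 0.34 with an estimated correlation), with Pou4f2 at 17.8 ± 0.806 CPM (6.89, SE 0.64) and Isl1 at 47.9 ± 11.3 (4.7, SE 0.47). For amacrine cells 10 of 13 rose, 11 when adjusted over the list alone (median 2.79, or 2.68 with floors, adjusted p = 4.8e-05, and 0.089 with an estimated correlation). The vesicular GABA transporter Slc32a1 was at least 120-fold higher (6.47 ± 1.73 CPM), and Gad2, which makes GABA, rose to 22.6 ± 6.61 CPM (5.94, SE 0.43). Horizontal cell genes had 4 of 5 higher, 5 alone (median 2.31, adjusted p = 0.0077, and 0.089 with an estimated correlation). Bipolar genes had 9 higher of 13 and 1 lower (median 2.35, adjusted p = 0.0029, and 0.013 with an estimated correlation). Pcp2 rose to 51 ± 14.2 CPM (8.09, SE 0.4), whereas Trpm1 fell from 870 ± 79.8 to 29.2 ± 3.07 (−4.9, SE 0.64). In the Müller glia list 6 of 13 rose and 3 fell (median 0.57, adjusted p = 0.033, and 0.13 with an estimated correlation), with Dkk3, a secreted protein also made by progenitors, rising to 1180 ± 133 CPM (5.05, SE 0.34) and Rlbp1 falling from 50 ± 3.97 (−2.29, SE 0.41).

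Progenitor genes rose for 7 of 12 (median log2 2.76, adjusted p = 1.1e-05, and 0.044 with an estimated correlation). Fgf15, a growth factor of progenitors, rose to 745 ± 167 CPM (5.07, SE 0.38), and Hes5, a Notch effector, to 60.7 ± 37.4 (3.46, SE 0.44). Hypoxia genes rose for 18 of 20, 19 alone (median 1.89, adjusted p = 1.1e-06, and 0.17 with an estimated correlation), among them Bnip3, a mitophagy receptor (451 ± 31.7 CPM at D18, 3.8, SE 0.44), and Ndrg1 (198 ± 25.6 CPM, 5.92, SE 0.39). Cholesterol genes were higher for 12 of 18 (median 0.81, adjusted p = 0.036, and 0.62 with an estimated correlation), and immediate early genes for 6 of 10 (median 1.54, adjusted p = 0.023, and 0.51 with an estimated correlation), where Btg2, also an antiproliferative gene of neurogenic divisions, was highest at 417 ± 29.3 CPM. Pluripotency genes fell further, 15 of 17 and 16 alone (median −3.11, adjusted p = 9.8e-10, and 0.0052 with an estimated correlation), and Tbx3, which also acts in the eye, rose (0.88, SE 0.31). The DNA replication genes Mcm4 and Mcm5 fell to 86.8 ± 22.5 and 105 ± 35.6 CPM (both −1.83), within a proliferation list with 15 of 24 lower (median −0.76, adjusted p = 9.4e-06, and 0.28 with an estimated correlation). Hindbrain genes were lower for 6 of 9 (median −3.51, adjusted p = 0.0079, and 0.13 with an estimated correlation), for example Hoxa2, with 0 counts at D18 and at least 46-fold lower.

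Among single genes outside these groups, Rd3l and Samsn1 were each at least 250-fold higher at D18, and Krt73, Samd7 and Lrit1 stood at 33.6 ± 20, 41.6 ± 13.6 and 16.2 ± 4.49 CPM from below 0.1. Lin28a, the RNA-binding protein of early progenitors (ENSMUSG00000050966), fell from 342 ± 46.6 to 1.48 ± 0.401 CPM (−7.85, SE 0.36, adjusted p = 1.5e-14). Other large falls were in Emx2 (46.7 ± 9.43 to 0.551 ± 0.233 CPM, −6.38), Wnt8b (−7.46), Rspo1 (−6.18), Dmrt3 (−6.77), Dmrta1 (−6.25) and Pax7 (−6.49). Of these Wnt8b, Rspo1 and Dmrt3 were lower in set 1 over D10 to D25 (−2.39, −1.77 and −1.92). Inmt, Dppa5a and Car4 fell as well, the last from 47 ± 8.56 to 0.015 ± 0.0261 CPM.

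Not passing camera were eye field genes (4 of 12 higher, adjusted p = 0.05), pigment epithelium (3 higher and 6 lower of 14, 0.11), mesendoderm (1 and 1 of 4, 0.96), fibroblast (1 and 4 of 13, 0.19), telencephalon (1 and 3 of 8, 0.25), lens (2 and 2 of 6, 2 and 3 alone, 0.56), neural crest (4 and 1 of 11, 0.47), retinoid (6 and 3 of 11, 0.56), and amino acid and ER stress (6 and 1 of 11, 0.47). Signs differed for microglia (2 and 1 of 5, median −0.3, mean 1.05, test upward, 0.78), endothelium (2 and 1 of 6, median −0.99, mean 0.21, test upward, 0.96) and mitochondrially encoded genes (2 of 9 higher, 0 alone, median −0.05, mean 0.21, test upward, 0.87). Mitf, the pigment cell factor, fell from 122 ± 14.7 to 4.4 ± 0.735 CPM, and Kdr, a VEGF receptor, rose from 23.6 ± 1.75 to 219 ± 43.6. In all, 9761 genes changed, 5338 higher and 4423 lower at D18. D7 lies wholly in set 1, and a model with the set gave 9357 changed genes.

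Which genes marked the maturation from D18 to D32? Rod genes rose without exception: all 15 were higher (median log2 7.11, adjusted p = 1.2e-27, and 0.00036 with an estimated correlation). Cnga1, a subunit of the rod channel, went from 0.015 ± 0.0261 to 218 ± 45.1 CPM. The calcium sensor Rcvrn (ENSMUSG00000020907, chromosome 11, 67695326 to 67703333) reached 358 ± 58.2 CPM (8.76, SE 0.45, adjusted p = 1.8e-13), the exchanger Slc24a1 209 ± 30.9 (8.79, SE 0.48) and the channel subunit Cngb1 437 ± 90.3 (7.5, SE 0.58, with a set 1 excess of 1.28). Proliferation genes fell, 24 of 24 (median −4.02, adjusted p = 1.2e-64, and 0.00014 with an estimated correlation), with Mki67 falling to 20.4 ± 2.84 CPM (−4.57).

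The outer segment list rose for 14 of 14 (median log2 3.5, adjusted p = 2.7e-22, and 0.00036 with an estimated correlation), as in Impg1 of the matrix around photoreceptors (163 ± 26.3 CPM, 8.21, SE 0.51), the retinol dehydrogenase gene Rdh12 (286 ± 38.8, 6.72, SE 0.24) and Rp1 (1070 ± 159, 5.92, SE 0.43, with a set 1 excess of 0.93). Ribbon synapse genes were higher for 13 of 15, 14 alone (median 2.23, adjusted p = 2e-13, and 0.0019 with an estimated correlation), including the calcium channel Cacna1f (95 ± 19 CPM, 5.58, SE 0.33) and Stx3, a fusion protein gene of the ribbon synapse (553 ± 88.4, 3.21, SE 0.22). Bipolar genes rose for 12 of 13 (median 2.5, adjusted p = 1.4e-09, and 4.8e-05 with an estimated correlation). Grm6 went from 0.35 ± 0.104 to 79.6 ± 8.36 CPM (7.8, SE 0.34), Cabp5, a calcium-binding protein gene of bipolar cells, to 34.1 ± 5.53 (5.43, SE 0.6), and the transcription factor Vsx1 to 6.08 ± 0.413 (4.85, SE 0.54). Müller glia genes had 8 of 13 higher and 3 lower (median 1.98, adjusted p = 0.015, and 0.083 with an estimated correlation). Rlbp1 and the potassium channel Kcnj10 rose to 164 ± 37.1 and 12.5 ± 2 CPM (4.01, SE 0.43 and 2.97, SE 0.37), while Dkk3, Sox9 and Glul fell (−1.58, −0.88 and −0.59).

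Progenitor genes fell for 11 of 12 (median log2 −1.91, adjusted p = 5.7e-08, and 0.012 with an estimated correlation). Fgf15 (ENSMUSG00000031073, chromosome 7, 144896531 to 144900953) went from 745 ± 167 to 3.39 ± 1.7 CPM (−7.78, SE 0.44) and Ccnd1 from 862 ± 111 to 58.7 ± 8.78 (−3.88, SE 0.33). Neurogenic genes were lower for 10 of 14 and higher for Neurod1, which also acts in photoreceptors (0.77, SE 0.24), with a list median of −3.02 (adjusted p = 1.6e-08, and 0.03 with an estimated correlation). Atoh7 fell to 0.113 ± 0.0997 CPM (−8.15, SE 0.44) and Foxn4 to 2.54 ± 0.6 (−5.67, SE 0.33). Ganglion cell genes were lower for 11 of 16, 12 alone, and higher for 2 (median −1.35, adjusted p = 0.019, and 0.71 with an estimated correlation). Pou4f2 fell to 0.294 ± 0.199 CPM (−5.9, SE 0.57), while Nefh and Thy1, which other neurons also make, rose (2.6, SE 0.36 and 2.45, SE 0.59). The retinoid list had 5 of 11 lower and 1 higher (median −0.45, adjusted p = 0.028, and 0.32 with an estimated correlation), with Crabp2 at 4.59 ± 1.08 CPM from 176 ± 15.9. Cholesterol genes fell for 14 of 18 (median −1.02, adjusted p = 0.00089, and 0.71 with an estimated correlation).

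Further large rises were in the GABA receptor Gabrr1 of bipolar cells (39.1 ± 1.97 CPM, 8.02, SE 0.69) and Tnnt2 (19.4 ± 5.62, 7.57, SE 0.64). Krt73, Fgf3, Fndc3c1, Ska1 and Dlx1 were among the largest falls (−7.64, −7.07, −6.32, −5.24 and −5). Cone genes did not pass as a list (3 higher and 5 lower of 13, 6 lower alone, median −0.7, adjusted p = 0.33): the phosphodiesterase Pde6c fell from 39.6 ± 15.8 to 1.78 ± 0.561 CPM (−4.47, SE 0.47) and Gnat2 fell as well (−1.83), while Gnb3 rose to 676 ± 38.9 (1.65, SE 0.28). Amacrine genes had 6 of 13 higher and Ptf1a lower (−6.78, SE 0.7), with a list adjusted p of 0.21, and Gad1 rose from 8.14 ± 5.02 to 121 ± 12.9 CPM (3.9, SE 0.37). Photoreceptor factors had 5 higher and 2 lower of 10 (0.24), with Nrl at 819 ± 114 CPM (4.5, SE 0.34) and Prdm1 lower (−2.36, SE 0.28).

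Of the remaining lists none passed: eye field (1 higher and 8 lower of 12, 9 lower alone, adjusted p = 0.11), horizontal cell (1 and 2 of 5, 0.76), pigment epithelium (2 of 14 lower, 1 alone, 0.5), fibroblast (1 of 13 lower, 0.95), telencephalon (2 of 8 lower, 0.47), hindbrain (3 of 9 higher, 0.16), microglia (1 of 5 lower, 0.76), neural crest (2 and 2 of 11, 2 and 1 alone, median 0, 0.76), hypoxia (8 and 4 of 20, 0.55), amino acid and ER stress (3 and 3 of 11, 0.76), immediate early (1 and 3 of 10, 0.85) and mitochondrially encoded (1 and 1 of 9, 1 higher alone, 0.85). Signs differed for pluripotency (1 and 3 of 17, median −0.2, mean −0.54, test upward, 0.84), mesendoderm (1 of 4 lower, median 0.1, mean −0.11, test downward, 0.85), lens (1 of 6 higher, median −0.75, mean 0.01, test downward, 0.85) and endothelium (2 and 1 of 6, median 0.2, mean −1.16, test upward, 0.85). In all, 8822 genes changed, 4101 higher and 4721 lower at D32 (4096 and 3752 with library size only). D32 lies wholly in set 2, and a model with the set gave 9036 changed genes and set 2 libraries alone 7284.

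Which of the steps between consecutive days carried these changes? The steps from D0 to D10 and the last step changed the most genes, at least 4591 each, and those between D10 and D25 at most 1631. The last step spans 7 days and holds the medium change at D26, while the other steps span 2 to 4 days. Per day it changed 656 genes in the main fit, against 2507 to 2838 in the steps from D0 to D10 and 164 to 492 in those between D10 and D25. Counts between D10 and D25 depended strongly on the fit, and several rose without the D4 libraries, as given below. The order per day of the last step and those steps is therefore that of the main fit. Replicate libraries of the same number moved together from D10 to D25: their residual correlations across days had a median of 0.208 over 45 pairs, against −0.124 over 90 pairs of different number. For the 5 steps within that range, values with the replicate number as a block therefore stand beside the counts. On these days replicate 2 was set 1 and replicates 1 and 3 were set 2. A set difference can thus give part of these correlations, and the block also takes up the set.

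**Figure D5:**
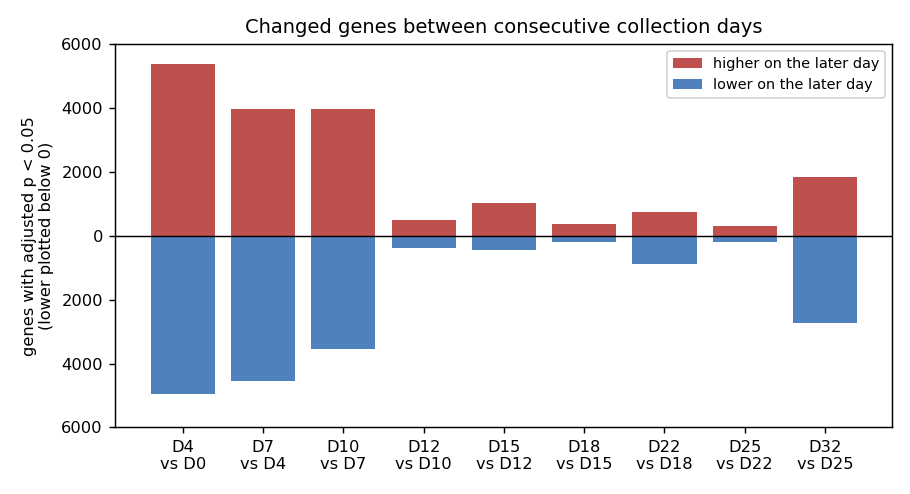
Genes changed between consecutive days, with those lower on the later day plotted below 0. The step from D0 to D4 had 10320 changed genes and that from D22 to D25 had 491.

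From D0 to D4 pluripotency genes fell first: all 17 were lower (median log2 −5.06, adjusted p = 2.3e-33, and 4.2e-06 with an estimated correlation), such as Klf4 (309 ± 7.81 to 2.09 ± 0.301 CPM, −7.21, SE 0.51, with a set 1 excess of 1 over D10 to D25). Eye field genes rose for 9 of 12 (median 4.95, adjusted p = 0.00012, and 0.37 with an estimated correlation), with Lhx2 at 70.3 ± 83.3 CPM (6.93, SE 0.72) and the list higher in replicate 3 than in the other D4 libraries (median 2.35). Foxd4, Fezf1 and Wnt1 had no counts at D0 and were at least 650, 550 and 260-fold higher. Feeder and immediate early genes moved with the pluripotency list, 10 of 13 and 9 of 10 lower (adjusted p = 0.0041 and 0.00012, and 0.54 for both with an estimated correlation). Col1a1 fell to 6.91 ± 3.88 CPM and Egr1 to 5.72 ± 6.88. Ptgs2, Vwa3b and the growth factor Ereg fell too, the first from 84.2 ± 28 to 0.251 ± 0.15 CPM (−8.28, SE 0.67). In all, 10320 genes changed, 5380 higher and 4940 lower (3664 and 5833 with library size only), and 9050 with the set as a term. D0 lies wholly in set 1 and D4 in set 2, so the set term rests on the differences within D10 to D25.

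From D4 to D7 pigment genes rose, 9 of 14 (median log2 3.52, or 3.55 with floors, adjusted p = 1.9e-06, and 0.26 with an estimated correlation). Dct rose from 0.0932 ± 0.116 to 164 ± 7.94 CPM (10.55, SE 0.51) and Pmel, a melanosome matrix protein gene, from 4.58 ± 1.88 to 598 ± 89.4 (7.01, SE 0.67, with a set difference of −1.07 over D10 to D25). Inmt reached 71.1 ± 3.02 CPM (9.11, SE 1.02) and Tspan10 27.9 ± 8.12. Hesx1, a forebrain repressor, went from 91.1 ± 87.2 to 0.0352 ± 0.0305 CPM, Foxd4 from 37.5 ± 30.7 to 0.0172 ± 0.0299, and Fgf5, a marker of the epiblast, fell from 32.8 ± 27.1 to 0.145 ± 0.0365 (−7.76, SE 0.96). Proliferation genes fell for 22 of 24, 23 alone (median −0.88, adjusted p = 4.6e-09, and 0.26 with an estimated correlation) and hypoxia genes for 11 of 20 (median −1.29, adjusted p = 8e-04, and 0.45 with an estimated correlation), with Ldha, lactate dehydrogenase, going from 5710 ± 2410 to 1710 ± 234 CPM. In all, 8515 genes changed, 3977 higher and 4538 lower (6550 and 1921 with library size only), 6759 with the set as a term and 4583 from the 6 libraries alone. Here too the days lie in different sets.

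From D7 to D10 neurogenic genes rose for 11 of 14 (median log2 3.12, adjusted p = 1.3e-19, and 0.0012 with an estimated correlation) and progenitor genes for 10 of 12 (1.98, adjusted p = 3.9e-10, and 0.0082 with an estimated correlation). Atoh7 reached 48.6 ± 10.8 CPM from 0.018 ± 0.0311, Foxn4 rose to 103 ± 1.99 (7.42, SE 0.39), Pou4f2 to 26.3 ± 1.44 (7.45, SE 0.64) and Rax to 146 ± 29.9 (2.47, SE 0.57). Hypoxia genes rose for 18 of 20, 19 alone (1.9, adjusted p = 7.7e-12, and 0.095 with an estimated correlation), with Ddit4, a stress inhibitor of mTORC1, going from 44.6 ± 2.28 to 337 ± 56.3 CPM (2.92, SE 0.58). Cholesterol genes rose for 17 of 18, 18 alone (1.11, adjusted p = 6e-07, and 0.35 with an estimated correlation), as in Insig1, a sterol sensor (82.7 ± 12.7 to 251 ± 24.9 CPM). Pluripotency genes fell for 13 of 17, 14 alone, and rose for 1 (−2.96, adjusted p = 7.1e-12, and 0.0012 with an estimated correlation). Mitochondrially encoded genes fell for 5 of 9 (−0.89, adjusted p = 0.016, and 0.66 with an estimated correlation), and Car4, Inmt and the neural factor Sox1 fell (−7.2, −6.28 and −6.15). In all, 7522 genes changed, 3979 higher and 3543 lower, and 6945 with the set as a term.

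From D10 to D12 all 9 mitochondrially encoded genes rose (median log2 1.44, adjusted p = 2.2e-16, and 0.14 with an estimated correlation). The cytochrome b gene mt-Cytb went from 1190 ± 204 to 3410 ± 465 CPM (1.52, SE 0.22) and mt-Nd2 of complex I from 652 ± 154 to 2300 ± 712 (1.82, SE 0.35). Hypoxia genes fell for 5 of 20, 13 alone (−0.74, adjusted p = 8.4e-09, and 0.3 with an estimated correlation), with Vegfa, the angiogenic factor, going from 390 ± 5.06 to 197 ± 52.7 CPM (−0.98, SE 0.24). Retinoid genes rose for 4 of 11, 6 alone (0.79, adjusted p = 0.00041, and 0.24 with an estimated correlation). Cyp26a1 and Dhrs3, enzymes that limit retinoic acid, rose to 46.6 ± 30.6 and 19.6 ± 14.5 CPM (3.18, SE 0.72 and 3.83, SE 0.51), and the labels give 9-cis retinal in the medium from D10. Gli1, a hedgehog target, rose as well (3.23, SE 0.48), while Postn, Tnfaip3 and Pax2 fell (−2.83, −2.43 and −2.22). Pigment genes fell for 4 of 14 (8 lower and 1 higher alone, −1.09, adjusted p = 0.00041, and 0.35 with an estimated correlation).

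In all, 878 genes changed at this step, 501 higher and 377 lower (turned to 307 and 378 with RLE factors, 117 and 319 with library size only and 342 and 518 from the 6 libraries alone), 1090 with the set as a term and 897 with the block. This count rested on the fit more than any other: it was 13 from set 2 libraries alone, and 2529 with the block and 1723 without it when only D10 to D25 were fitted. Leaving out the D4 libraries gave 2134, DESeq2 1592, library size in place of TMM factors 436 and no expression filter 485. Without 1 library of the pair it was 208, 401 or 133 (D10 replicates 1, 2 and 3) and 381, 492 or 347 (D12 replicates 1, 2 and 3).

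From D12 to D15 photoreceptor factors rose for 8 of 10, 10 alone (median log2 1.42, adjusted p = 2.6e-21, and 5e-04 with an estimated correlation), with Crx going from 39.3 ± 11.9 to 247 ± 23.3 CPM (2.65, SE 0.32). Cone genes rose for 8 of 13, 10 alone (1.65, adjusted p = 1.2e-15, and 0.0014 with an estimated correlation), outer segment genes for 7 of 14, 8 alone (2.2, or 1.85 with floors, adjusted p = 1.5e-15, and 0.0023 with an estimated correlation) and neurogenic genes for 10 of 14, 13 alone (1.26, adjusted p = 5.2e-16, and 0.0023 with an estimated correlation). Rbp3, the retinoid carrier of the photoreceptor matrix, rose from 19.1 ± 4.65 to 210 ± 47.5 CPM (3.46, SE 0.27). Amino acid and ER stress genes rose for 6 of 11, 7 alone (0.84, adjusted p = 1.8e-08, and 0.016 with an estimated correlation). Amacrine genes rose for 7 of 13 (1.53, adjusted p = 1.1e-06, and 0.04 with an estimated correlation). Tmem92 and Gjd2, the neuronal connexin, rose by 4.43 and 3.68, and Lin28a, Gli1 and Tspan10 fell (−2.58, −2.48 and −2.31, the last with a set difference of −0.93). In all, 1475 genes changed, 1020 higher and 455 lower, 1622 with the set as a term, 1532 with the block and 2803 with the block over D10 to D25. Set 2 alone gave 547, a fit without D4 2328, library size in place of TMM 982, and leaving out D12 replicate 1, D12 replicate 3 or D15 replicate 3 gave 976, 907 or 805.

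From D15 to D18 cone genes rose for 7 of 13, 10 alone (median log2 1.55, adjusted p = 3.9e-14, and 0.0014 with an estimated correlation), and outer segment genes for 8 of 14, 10 alone (1.44, adjusted p = 2e-22, and 9e-04 with an estimated correlation). Nr2e3 rose from 0.564 ± 0.349 to 24.1 ± 14 CPM (5.4, SE 0.54), Nrl from 5.37 ± 2.79 to 36.3 ± 11.7 (2.76, SE 0.33), and Rp1 and Samd7 by 4.54 and 3.45. Amacrine genes rose for 3 of 13, 9 alone (1.01, adjusted p = 1.8e-08, and 0.019 with an estimated correlation), led by Gad1 (0.927 ± 0.119 to 8.14 ± 5.02 CPM, 3.12, SE 0.43). Lin28b, Fgfbp3 and Aldh1a7 fell (−1.78, −1.89 and −1.88). In all, 575 genes changed, 381 higher and 194 lower, 713 with the set as a term, 651 with the block, and 1344 with or 875 without the block over D10 to D25. Set 2 alone gave 182, a fit without D4 1061, DESeq2 982, and leaving out D15 replicate 1 or 3 or D18 replicate 2 or 3 gave 246, 309, 296 or 314.

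From D18 to D22 rod genes rose for 13 of 15, 14 alone (median log2 3.27, adjusted p = 1.9e-32, and 0.00054 with an estimated correlation), with Pde6b, a subunit of the rod phosphodiesterase, going from 5.45 ± 2 to 165 ± 73.8 CPM (4.92, SE 0.37). Bpifb6 rose by 5.14. Proliferation genes fell for 22 of 24, 24 alone (−1.07, adjusted p = 5e-37, and 0.0023 with an estimated correlation), as in Top2a (560 ± 65 to 219 ± 45.1 CPM). Ganglion cell genes fell for 10 of 16 and Nefh rose (−1.35, adjusted p = 1e-07, and 0.14 with an estimated correlation), with Pou4f2 going from 17.8 ± 0.806 to 1.74 ± 0.681 CPM. Atoh7 and Fgf3 fell (−2.83 and −2.67). In all, 1631 genes changed, 747 higher and 884 lower (636 and 557 with library size only), 1819 with the set as a term, 1723 with the block and 2709 with the block over D10 to D25. Set 2 alone gave 535, and leaving out D22 replicate 2 gave 938.

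From D22 to D25 rod genes rose for 12 of 15, 13 alone (median log2 1.64, adjusted p = 2.6e-25, and 0.00079 with an estimated correlation) and outer segment genes for 11 of 14, 13 alone (1.23, adjusted p = 1.5e-23, and 0.00063 with an estimated correlation). Cnga1 rose from 2.83 ± 1.95 to 32.8 ± 11.1 CPM (3.53, SE 0.41) and Impg1 by 2.67. Fgf15 fell from 159 ± 39.2 to 30.7 ± 13.2 CPM (−2.37, SE 0.34), as did the melanosomal gene Gpnmb (−2.06, SE 0.54, with a set difference of −0.93) and Eda2r (−2.06, SE 0.41). The retinoid list fell with 1 changed member, Crabp2, 3 alone (−0.59, adjusted p = 2.3e-05, and 0.039 with an estimated correlation). In all, 491 genes changed, 288 higher and 203 lower (133 and 154 with library size only), 639 with the set as a term, 544 with the block, and 1381 with or 745 without the block over D10 to D25. Set 2 alone gave 68, a fit without D4 1009, the 6 libraries alone 120, DESeq2 1024, limma on the deposited CPM 819 and library size in place of TMM 287. Leaving out D22 replicates 1, 2 or 3 gave 75, 749 or 214, and D25 replicates 1 or 2 gave 288 or 92.

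From D25 to D32 bipolar genes rose for 12 of 13 (median log2 2.21, adjusted p = 1.3e-19, and 1.1e-07 with an estimated correlation). Grm6 went from 0.343 ± 0.151 to 79.6 ± 8.36 CPM (7.83, SE 0.34), Scgn, a calcium-binding protein gene of cone bipolar cells, from 0.901 ± 0.248 to 37.6 ± 2.65 (5.37, SE 0.49), and the factor Bhlhe23 from 0.0314 ± 0.0272 to 28.5 ± 3.84. Gabrr1 rose by 7.66. Proliferation genes fell for 24 of 24 (−2.54, adjusted p = 5.8e-74, and 9.5e-05 with an estimated correlation) and neurogenic genes for 12 of 14 (−1.9, adjusted p = 1.2e-13, and 0.0092 with an estimated correlation). Rod genes rose for 11 of 15, 12 alone (1.47, adjusted p = 1.4e-12, and 0.016 with an estimated correlation), such as Rcvrn (33.6 ± 11.7 to 358 ± 58.2 CPM).

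Cone genes fell for 6 of 13 at this last step (median log2 −0.84, adjusted p = 0.0019, and 0.2 with an estimated correlation). Opn1sw went from 77.7 ± 39.9 to 4.75 ± 3.06 CPM (−4.03, SE 0.55), Gngt2 from 567 ± 210 to 112 ± 4.91 (−2.34, SE 0.36) and Pde6c from 9.99 ± 4.24 to 1.78 ± 0.561 (−2.48, SE 0.45), while Gnb3 (630 ± 191 and 676 ± 38.9) did not pass. Krt73 and AA623943 fell (−6.92 and −3.62). In all, 4591 genes changed, 1852 higher and 2739 lower (1827 and 1630 with library size only), 4703 with the set as a term and 3087 from set 2 libraries alone.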

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

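The transcript comparison and the splits between pairs of days were chosen after results were seen, whereas the splits over all 10 days were planned before. In the transcript table, which enters no comparison of the report, 1958 of 18189 transcripts changed their share of their gene between D10 and D25 (limma on arcsine-root shares with the library set as a term, Benjamini-Hochberg adjustment). This is a signal in a part of the data that the comparisons above do not use, and its genes are described among the observations below. In simulated shares 53% of the smaller and 83% of the larger shifts were recovered, with 12 false calls. Simulated transcripts varied independently of each other, whereas real shares within a gene depend on each other.

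When the 30 libraries were split at random into 10 groups of 3, the real days gave 18178 changed genes, and 1 of 100 splits (the real one included) was as large, with 6747 as the highest other value, so random grouping of the libraries is not a likely source of that count. Each pair of days allows only 10 splits of its 6 libraries, too few for a share under 0.05. The number of splits as large as the real one was 1 for the changed genes of D7 vs D0 (real 11622, highest other 3), D18 vs D7 (9761 and 0), D32 vs D18 (8822 and 0), D4 vs D0 (10320 and 1410), D7 vs D4 (8515 and 2491), D10 vs D7 (7522 and 0), D12 vs D10 (878 and 0), D15 vs D12 (1475 and 1), D18 vs D15 (575 and 1), D22 vs D18 (1631 and 1), D25 vs D22 (491 and 0) and D32 vs D25 (4591 and 0). For the lists called it was 2 in D7 vs D0 (real 11, highest other 13), 1 in D18 vs D7 (18 and 17) and 7 in D32 vs D18 (11 and 15). Every other split of a pair still has more libraries of one day on one side, so part of the day difference remains. The list counts of those splits are therefore not the level that random grouping alone would give.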

How the results depend on the processing

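The fits without D4 or D4 replicate 2, those to D10 to D25 alone and those with library sets were chosen only after results had been seen. No call that was checked turned its direction: over 584 results of named genes, 10759 of 11085 alternative values kept the call, 230 lost it and 96 gained it, and 486 results kept direction and call in every alternative. These results cover the largest changes of spans and steps, and the list members and markers of the spans. List members named only for a step were not checked. Many of the genes checked were picked for a large change, which favours a stable call. The count over all 10 days (18178) and those of D7 vs D0 (11622), D18 vs D7 (9761), D32 vs D18 (8822), D4 vs D0 (10320) and D32 vs D25 (4591) moved by less than 1.5 times in every setting. Steps between D10 and D25 moved most. D12 vs D10 (878) gave 436 with library size only, 1592 with DESeq2, 485 with no filter, 2134 without D4, 2529 with and 1723 without the replicate block over D10 to D25, 13 in set 2, and 208, 401 and 133 without D10 replicates 1, 2 and 3 or 381, 492 and 347 without D12 replicates 1, 2 and 3. D15 vs D12 (1475) gave 982 with library size only, 2328 without D4, 2803 with the block over D10 to D25, 547 in set 2, and 976, 907 and 805 without D12 replicate 1, D12 replicate 3 and D15 replicate 3. D18 vs D15 (575) gave 982 with DESeq2, 1061 without D4, 1344 with and 875 without the block over D10 to D25, 182 in set 2, and 246, 309, 296 and 314 without D15 replicates 1 and 3 and D18 replicates 2 and 3. D22 vs D18 (1631) gave 2709 with the block over D10 to D25, 535 in set 2 and 938 without D22 replicate 2. D25 vs D22 (491) gave 287 with library size only, 1024 with DESeq2, 819 with limma on log2(CPM + 1), 120 from the 6 libraries of the 2 days, 1009 without D4, 1381 with and 745 without the block over D10 to D25, 68 in set 2, and 75, 749, 214, 288 and 92 without D22 replicates 1, 2 and 3 and D25 replicates 1 and 2. Without D4 replicate 2 these 5 steps gave 1004, 1609, 655, 1785 and 564. D7 vs D4 (8515) gave 4583 from its 6 libraries, and 6581 to 10126 when 1 library was left out. D10 vs D7 (7522) gave 4266 in set 1, which holds 1 library of D10. The number of lists called went from 11 to 1 with an estimated correlation and 25 with fry in D7 vs D0, from 18 to 8 and 26 in D18 vs D7, and from 11 to 7 and 18 in D32 vs D18, while leaving out a library gave 10 to 12, 16 to 19 and 11. The fry counts answer another question, as fry tests a list against no change and not against all other genes. With library size only, the share of changed genes that were higher went from 52.1 to 38.6% in D4 vs D0, 46.7 to 77.3% in D7 vs D4, 52.9 to 64.9% in D10 vs D7, 57.1 to 26.8% in D12 vs D10, 66.3 to 86.7% in D18 vs D15, 58.7 to 46.3% in D25 vs D22 and 40.3 to 52.8% in D32 vs D25. The majority turned as well in D7 vs D0 (49.3 to 58%), D32 vs D18 (46.5 to 52.2%) and D22 vs D18 (45.8 to 53.3%). Fits restricted to a set or short of a library also hold fewer libraries, which lowers their power by construction. The cause was not tested for any of the other changes.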

Other observations

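Apart from the mitochondrial read, D7 mixture and D4 pace tests, the tests below were chosen only after the result was seen, as were the transcripts and genes named here. Between D10 and D25, the estimated shares of transcripts within their gene changed in ways that the gene counts do not show. These are shares of estimated counts, not corrected for transcript length. The error of dividing reads between similar transcripts did not enter the test. The largest shifts were in Filip1l, where Filip1l-003 went from 90.2 ± 1.6 to 11.2 ± 8% of its counts (n = 3, adjusted p = 5.8e-07), Pim2 and Tenm1, and the genes below were picked for their known roles. Ttc8, a gene of the ciliary BBSome complex, moved to a transcript (Ttc8-002) that went from 0% of its counts at D10 to 54.6 ± 14.7% at D25 (adjusted p = 4.1e-06). Dmd, the dystrophin gene, moved to Dmd-001 (9.8 ± 0.5 to 77.8 ± 3%), the endocytosis gene Bin1 to Bin1-201 (33.7 ± 2 to 87.7 ± 3%), the neurotrophin receptor gene Ntrk2 to Ntrk2-201 (11.5 ± 1.1 to 65.2 ± 11.7%) and the presynaptic SNARE gene Stx1a to Stx1a-001 (16.9 ± 5 to 73.2 ± 6.4%). In all, 1160 of 5839 genes had a changed transcript, and in 124 genes one transcript gained and another lost at least 25 percentage points. The threshold and the pair of days were set after a look at other days.

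Between D10 and D25 replicate 2 differed from replicates 1 and 3 in 861 genes, against 235 for replicate 3 and 0 for replicate 1 set against the others. Of 7 such genes looked at on D0, D4, D7 and D32, every library followed its set for 6 (Meg3, Rian, Duxbl1, Slc7a11 and the Y-linked genes Uty and Eif2s3y), as in Uty with 3.91 ± 1.86 CPM in set 1 (n = 6) and 18.6 ± 3.42 in set 2 (n = 12) over D10 to D25, 4.42 ± 0.572 at D0 and 23 ± 6.47 at D32 (n = 3), but not for Mid1, with 224 ± 11 at D32 in set 2 against 210 ± 14 at D0 in set 1. Counts split differently between genes and their named copies are unlikely as the whole cause. Of the differing genes 69.7% (600) had no named copy and were neither pseudogenes nor predicted genes. Among these 600, 106 differed by an absolute log2 of at least 1. A different split stays open for Rpl3, which defined the sets, and Rpl34, with sums that differed by −0.12 and 0.04 only. Only copies named after their gene were counted, so sharing of reads with other copies was not tested and may reach some of the 600. A faster pace in set 1 is unlikely as the whole cause, since differences followed the D10 to D25 change with r = 0.23 only. Pace may still have a part, as replicate 2 lay nearest to the following day on D15 and D22, and this was not tested. The 98.3% of calls kept without mitochondrial and ribosomal RNA genes decide nothing. Those genes held at most 5.26% of the counts, too few to move the calls. Another clone, passage or sequencing run remains possible, the labels name 1 clone, and none of these was tested.

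At D4, replicate 3 lay nearest to D7, with eye field and all 8 telencephalon genes higher (median log2 2.35 and 1.05) and all 18 cholesterol, all 9 mitochondrially encoded and 21 of 24 proliferation genes lower (−1.2, −1.13 and −0.41) than in the other D4 libraries, each in the direction of the list's median change from D4 to D7. Not every list lay towards D7: endothelium genes were higher in replicate 3 (median 1.23, 1 of 6 lower), while their mean log2(CPM + 1) went from 1.64 at D4 to 1.47 at D7. RNA of D7 organoids in that library could place it near D7, but genes abundant at D7 did not appear at a common share of their D7 level: the 10th percentile was 1.49% and the median 15.65% over 128 genes. A culture running ahead may be the source instead, and the pluripotency list was to show it by lower values. Its median was 0.08, which met the bound set beforehand against this explanation (at or above 0), but with quartiles of −0.41 and 0.41 its members go both ways. The bound was therefore widened to the quartiles after the value was seen, and the question stays open.

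From D10 to D12 mitochondrially encoded genes rose and hypoxia genes fell, after oxygen and medium had changed together at D10. Scaling is an unlikely source of the mitochondrial rise, as the mitochondrial median was 1.3 with library size only. The oxygen level of the culture alone could have set the hypoxia list, but the list had risen from D7 to D10 at the same level (median 1.9). That rise argues against the culture level as the only influence on the list, while a part of oxygen in the fall at D12 stays open. The data hold no measure of oxygen within the tissue. The list was near its D10 level at D15 and D18 (0 and −0.11). At D12, D22 and D25, 3 of 5 days, it lay lower (−0.74, −0.55 and −0.44). Mitochondrial genes stayed above D10 throughout (0.84 to 1.55). Set 1 alone carrying the change is unlikely, as every pair of set 2 libraries had a mitochondrial median of at least 0.93 and a hypoxia median of −0.67 or lower. Set 2 alone was not excluded, since set 1 has 1 library a day (medians 1.41 and −0.54), the medium change was not tested separately, and a lower cell number per library, as organoids per library fell from 20 to 12, was not tested either.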
